A study of Ovis aries with 6 samples.

How the data were processed

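Nuclear RNA from the ventral-sac rumen epithelium of 6 male lambs was sequenced by 10x Genomics droplet libraries, 1 library per animal, with 3 animals in MGNS and 3 in MGHS per the labels. The labels state that separate sheep were picked at random from each group, so the animal is the replicate. Tissue was washed, chopped and frozen in liquid nitrogen before nuclei were isolated, per the labels' protocols. The deposited matrices hold whole-number UMI counts per gene and barcode without any scaling, per the file headers and the values themselves. The counts were made with Cell Ranger 8.0.0 per the file headers and with Cell Ranger 2.1.1 per the submitters' processing notes, and this difference was not resolved. The genome build, the annotation and the rule that kept barcodes are not given in the sources used here.

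Everything else was computed from those counts. CPM, percentages, log2 fold changes and scores are computed values, made here. The files identify genes by NCBI gene numbers without symbols, and 26741 of 26741 were matched to symbols from a gene table of the assembly ARS-UI_Ramb_v3.0, used for names only. Of these, 21300 are protein coding, 5441 are lncRNAs, 13 are mitochondrial and 10319 carry a placeholder LOC symbol. How the counting treated reads shared by near-identical genes or by overlapping genes on opposite strands is not given in the sources used here, so members of multigene families are less certain.

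Nuclei were kept with at least 300 genes and at most 10% mitochondrial UMIs, without the 0.5% of barcodes with the most UMIs in each library. Between 21.5% and 36.8% of a library's barcodes had under 300 genes. Over 10% mitochondrial UMIs were found in 328, 7 and 185 barcodes in MGNS 1 to 3 and 1414, 744 and 22 in MGHS 1 to 3. The filters left 5033, 8703 and 7701 nuclei in MGNS 1 to 3 and 6016, 6846 and 11184 in MGHS 1 to 3. Doublets were called per library with Scrublet in scanpy 1.11.5 (Python 3.11.15, seed 0). Where it called under 0.5%, as in MGNS 1 and MGNS 2, the top scores at 0.8% per 1000 nuclei were removed instead. In all 3956 doublets were removed, 203, 606 and 872 in MGNS 1 to 3 and 671, 534 and 1070 in MGHS 1 to 3. The median retained nucleus held 4764.5, 4061 and 3262 UMIs in MGNS 1 to 3 and 4198, 3975 and 3121 in MGHS 1 to 3. Median mitochondrial percentages of retained nuclei were 0.60, 0.29 and 0.50 in MGNS 1 to 3 and 0.72, 0.55 and 0.85 in MGHS 1 to 3.

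Counts were scaled to 10000 per nucleus and log transformed, and 2000 variable genes were chosen with the library as batch and scaled with a clip at 10. A graph was built from 30 principal components with 5 neighbours taken from each library, and Leiden clustering with igraph 0.11.9 at resolution 0.8 gave 24 clusters. Clusters were named from 17 marker lists by the log2 ratio of mean CPM against the other clusters, with 10 CPM added. Which cluster took which name was decided from the markers after clustering, and names end in "-like" because they rest on transcripts alone.

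Keratinocyte-like classes were basal-like (clusters 1 and 5), spinous-like (cluster 7), granular-like (clusters 3 and 9) and cycling (cluster 12). TP63 and KRT15 were among the 10 leading genes of cluster 5, DSG1 and DSC2 of cluster 7, and ANLN, CENPF and TOP2A of cluster 12. Cluster 3 had a mean log2 ratio of 1.39 for spinous and 1.31 for granular markers, and took its name because 8 granular markers against 5 spinous ones were at least 2-fold up. Cluster 7 also had 8 granular markers at 2-fold, with mean log2 ratios of 1.46 for spinous and 0.89 for granular markers, so the border between the 2 classes is uncertain. The other named classes were T or NK-like (clusters 2, 4 and 8), B or plasma-like (18 and 21), macrophage or dendritic-like (14 and 15), neutrophil-like (13), fibroblast-like (6 and 16), smooth muscle or pericyte-like (10 and 17), blood endothelial-like (11), lymphatic endothelial-like (20) and glia-like (23). Clusters 0, 19 and 22 were not named. In cluster 0 the keratinocyte genes KRT36 and KRTDAP were among the 10 leading genes, but no marker of a list was, and the median nucleus held 583 UMIs. Classes were fitted for genes where every animal had 20 nuclei, and an unnamed cluster where it held over 5% of nuclei, which gave 13 single classes. Glia-like nuclei and clusters 19 and 22 were compared by share alone.

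UMIs were summed per animal over all nuclei, over all keratinocyte-like nuclei and within each class. Genes were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr with a minimum count of 10, TMM, robust quasi-likelihood F test, MGHS against MGNS) and Benjamini-Hochberg adjustment at 0.05. DESeq2 1.42.0 and limma 3.58.1 (voom with sample quality weights) were run beside it. Lists were tested with camera at a preset correlation of 0.01 on each list with at least 5 tested members, over 31 function lists and separately over the marker lists, with estimated correlation and fry as alternatives. Differences between neighbouring layers were tested with limma on each animal's difference of log2 CPM with a prior count of 2. Shares and depth were compared by two-sided exact permutation of the 6 animals over 20 ordered splits.

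Tests, lists, filters, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, per comparison, genes with a symbol past an adjusted p of 0.05 whose groups do not overlap and whose mean log2 CPM is at least 4. It takes the 12 with the largest fold change per direction for all keratinocyte-like nuclei and 6 per direction for other classes, and permits up to 4 members per list with the smallest p in the all keratinocyte-like fit. SLC16A1, BDH1, SLC9A3, SLC4A2, SLC14A1, IGFBP5, KRT5, KRT6A and MKI67 are given in any case, and some other genes that the rule names are not reported here. Which of the permitted list members are named was chosen after their values were seen, as were GPX1 and IGFBP5 in basal-like nuclei, TMPRSS2, and the view of SELENOW and GPX1 over classes.

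Alternatives for genes were RLE size factors, no filter, a minimum count of 50, DESeq2, voom, the replicate number as a block, each animal left out, doublets kept, at least 600 genes, sums thinned to the smallest animal, resolutions 0.5 and 1.2 (20 and 26 clusters) and 30 ordinary nearest neighbours (26 clusters). Shares that leave cluster 0 out of the total, with or without MGHS 3, were chosen after seeing the data.

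The fits were tested on simulated counts with the real means and library sizes, where each gene took the dispersion of the fitted trend at its level. Scatter of real genes around that trend was not simulated, so the percentages called below need not hold for the real data. For all keratinocyte-like nuclei edgeR called 16% of genes changed 2-fold and 86.9% of those changed 4-fold among 16224 genes, with 6 false calls. The same test called 30% and 85.6% for basal-like, 6.3% and 54.5% for granular-like and 23.2% and 95.9% for B or plasma-like nuclei, with 8, 6 and 1 false calls. The test between layers called 7.2% and 61.9% for basal-like against spinous-like nuclei and 0% and 13.8% for spinous-like against granular-like nuclei. camera called the 1 changed list of 30 members and 0 of 20 random lists. The simulated genes were drawn independently of each other, so this does not test camera where members of a list move together. Animals of a group differed by far more than counting noise, with a chi-square per degree of freedom of 87.6 to 225 for sums over all nuclei. Pooled over genes, counting noise was thus a small part of the spread there, which does not show this for genes with few counts.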

Results

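Droplet single-nucleus RNA sequencing was carried out on the ventral-sac rumen epithelium, the keratinised forestomach lining that absorbs short-chain fatty acids. The nuclei came from 6 male lambs, 3 in a group named MGNS and 3 in a group named MGHS. The series concerns grazing sheep and supplementary feeding, the labels do not spell out either group name, and every difference is given as MGHS against MGNS. The files held 67553 barcodes and 268011559 UMIs over 26741 genes. Total UMIs per animal were 34418856, 54819907 and 40942515 in MGNS 1 to 3 and 38903073, 38929415 and 59997793 in MGHS 1 to 3. After filtering, 4830, 8097 and 6829 nuclei were retained in MGNS 1 to 3 and 5345, 6312 and 10114 in MGHS 1 to 3, 41527 in all. Values are means ± SD over 3 animals per group unless a standard error (SE) is named. Values given with an SE are log2 fold changes, also where a gene is said to rise or fall by them. That SE is the absolute log2 fold change divided by the square root of the F statistic.

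Depth was compared first, because counts per nucleus limit what can be detected. UMIs in retained nuclei summed to 35535000 ± 8534600 per animal in MGNS and 36583000 ± 9858600 in MGHS (two-sided exact permutation p = 0.6). The median nucleus held 4029.2 ± 751.76 UMIs in MGNS and 3764.7 ± 568.47 in MGHS (exact permutation p = 0.6), and 1865.5 ± 220.64 and 1681.3 ± 53.594 genes (exact permutation p = 0.4). These differences lay within the spread between animals. With 3 animals against 3, an exact permutation test cannot give a p under 0.1.

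The first question was which cell classes made up the epithelium in each group. Granular-like nuclei, whose border with spinous-like nuclei is uncertain, held 7.68 ± 1.90% of nuclei in MGNS and 14.7 ± 3.93% in MGHS, and cycling keratinocyte-like nuclei 2.16 ± 0.610% and 4.27 ± 1.56%. Spinous-like nuclei held 5.95 ± 1.37% and 3.58 ± 0.484%, and basal-like nuclei, the lowest layer, 14.4 ± 0.445% and 14.3 ± 4.80%. B or plasma-like nuclei held 5.19 ± 2.98% in MGNS and 1.01 ± 0.876% in MGHS, macrophage or dendritic-like nuclei 7.29 ± 0.841% and 5.13 ± 0.981%, and glia-like nuclei 1.12 ± 0.410% and 0.364 ± 0.171%. The unnamed cluster 19, where T and NK markers were raised beside BLK, held 3.04 ± 0.116% and 0.698 ± 0.261%. In each of these classes except basal-like, every MGHS animal lay on one side of every MGNS animal. Their exact permutation p was 0.1, the smallest possible, and 0.2 after adjustment over 16 classes and clusters, so no share passed. The higher granular-like share lay mainly in cluster 9, 1 of the 2 clusters of that class. Cluster 9 made up 19.2%, 4.93% and 15.5% of granular-like nuclei in MGNS 1 to 3 and 54.6%, 69.5% and 23.5% in MGHS 1 to 3. Cluster 3 held 235, 559 and 563 nuclei in MGNS 1 to 3 and 433, 308 and 798 in MGHS 1 to 3. Shares are parts of a whole and pull on each other.

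The other shares overlapped between the groups, except that of cluster 0, whose difference came largely from 1 animal. T or NK-like nuclei held 24.6 ± 4.49% and 15.3 ± 5.86%, neutrophil-like nuclei 3.86 ± 2.17% and 2.01 ± 1.60%, and the unnamed cluster 22, led by cycling genes with T or NK markers raised, held 1.03 ± 0.665% and 0.452 ± 0.111%. Fibroblast-like nuclei held 7.78 ± 3.44% and 8.83 ± 1.80%, smooth muscle or pericyte-like nuclei 5.37 ± 2.16% and 7.10 ± 1.00%, blood endothelial-like nuclei 3.13 ± 0.739% and 4.19 ± 1.16%, and lymphatic endothelial-like nuclei 1.75 ± 0.498% and 1.88 ± 0.603%. Cluster 0, an unnamed group with a median of 583 UMIs per nucleus and keratinocyte genes among its leading genes, held 5.65 ± 1.45% in MGNS and 16.2 ± 13.8% in MGHS, where MGHS 3 alone had 32.1%, and its log2 ratio of 1.52 was 0.54 without MGHS 3. For cluster 0 every MGHS animal lay above every MGNS animal (exact permutation p = 0.1, and 0.2 after adjustment). All keratinocyte-like nuclei held 30.2 ± 1.99% and 36.8 ± 5.90% (exact permutation p = 0.2). Counted without cluster 0, a choice made after seeing the data, they held 32.0 ± 1.67% and 44.0 ± 2.29%, granular-like nuclei 8.12 ± 1.88% and 17.4 ± 2.21%, and T or NK-like nuclei 26.1 ± 5.12% and 17.9 ± 4.67%. An edgeR fit on the nuclei counts called B or plasma-like nuclei lower (log2 fold change -2.37, adjusted p = 0.0311), as it did cluster 19 (-2.12, adjusted p = 0.00292) and glia-like nuclei (-1.64, adjusted p = 0.0311), each with every MGHS animal below every MGNS animal.

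**Figure D1:**
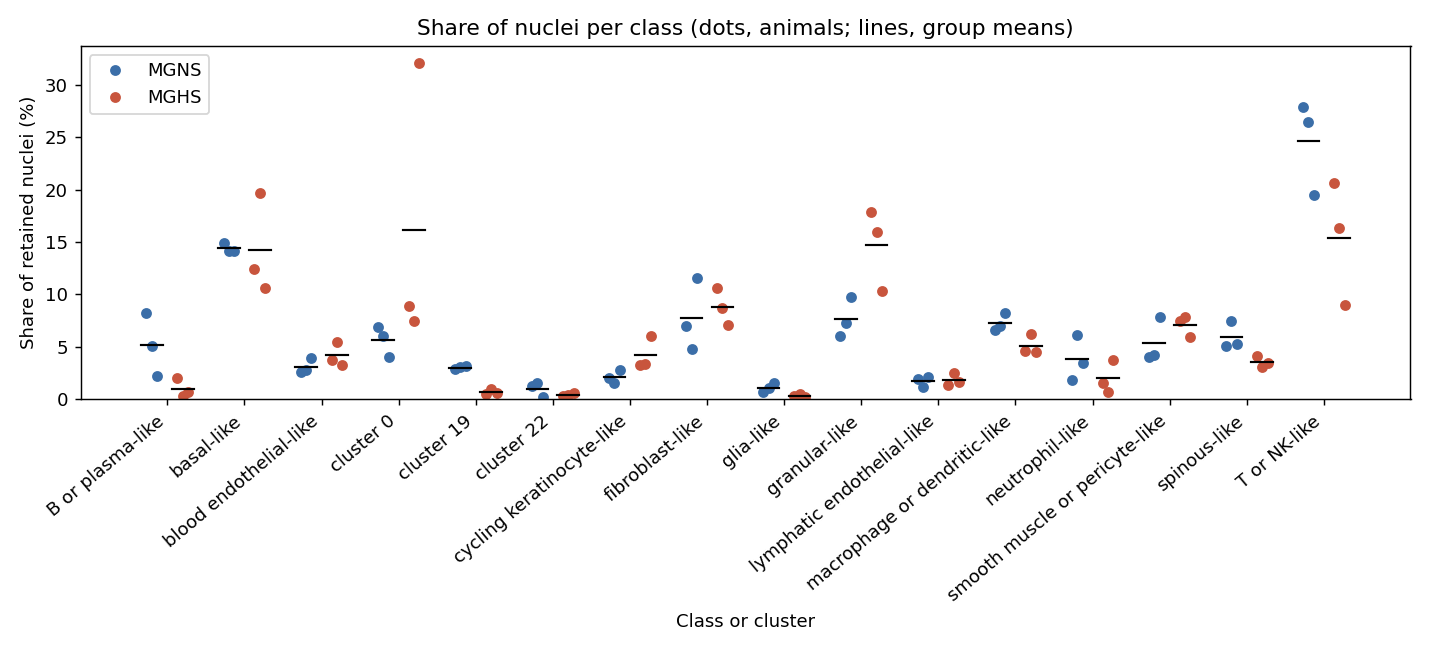
Percent of retained nuclei (vertical axis) in each class or cluster (horizontal axis) for 3 MGNS and 3 MGHS animals, with dots for animals and lines for group means. Granular-like nuclei averaged 7.68% in MGNS and 14.7% in MGHS, a difference that lay mainly in cluster 9, and MGHS 3 had 32.1% of its nuclei in cluster 0.

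The next question was which transcripts differed when the basal-like, spinous-like, granular-like and cycling nuclei, 13781 in all, were summed per animal as all keratinocyte-like nuclei. GPX1, a selenium-containing glutathione peroxidase, had 35.8 ± 12.8 CPM in MGNS and 226 ± 56.3 CPM in MGHS (log2 fold change 2.66 ± 0.33 SE). IGFBP5, which binds insulin-like growth factors, had 20.4 ± 7.31 and 79.8 ± 28.2 CPM (1.97 ± 0.34 SE). The sodium/proton exchanger SLC9A3 had 109 ± 20.1 and 282 ± 129 CPM (1.37 ± 0.38 SE), the monocarboxylate transporter SLC16A1 had 314 ± 127 and 583 ± 134 CPM (0.89 ± 0.35 SE), and the proliferation antigen MKI67 had 17.95 ± 1.70 and 30.9 ± 8.15 CPM (0.79 ± 0.22 SE). Every MGHS animal lay above every MGNS animal for these 5 genes, and none passed in edgeR (adjusted p = 0.110, 0.126, 0.170, 0.258 and 0.172 in that order). edgeR called 0 of 16369 genes (2876 at an unadjusted p under 0.05, smallest adjusted p 0.110), DESeq2 called 1024 (592 higher, 432 lower) and limma-voom 0. Without MGHS 3 edgeR called 180 (160 higher, 20 lower), with GPX1 (adjusted p = 0.0433, 2.16e-11 to 0.295 over 18 alternatives) and SLC9A3 (adjusted p = 0.0447, 0.0154 to 0.378) past the test. GPX1 passed in 3 of the 18 alternatives, SLC9A3 in 2, IGFBP5 and MKI67 in 1 each, by DESeq2, and SLC16A1 in 0. The groups did not overlap for 3939 genes, or 24.1%, where chance gives 10% on average over splits of the animals. Genes of an animal are not independent, so any given split can lie far from that average. The share was not computed for the other splits, here or in the classes below, so no excess over chance is shown.

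Genes of ketone, urea and bicarbonate handling and a pair of keratins did not pass in all keratinocyte-like nuclei either. BDH1, which interconverts ketone bodies, had a log2 fold change of 0.45 ± 0.21 SE (edgeR adjusted p = 0.318) with every MGHS animal above every MGNS animal. The urea transporter SLC14A1 had 1.53 ± 0.85 SE (adjusted p = 0.377), and the basal keratin KRT5 0.61 ± 0.35 SE (adjusted p = 0.390). KRT6A, a keratin of stressed epithelium, had 0.47 ± 0.33 SE (adjusted p = 0.476), and the bicarbonate exchanger SLC4A2 0.34 ± 0.26 SE (adjusted p = 0.521). The groups overlapped for the 4 genes other than BDH1.

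Of the lists in all keratinocyte-like nuclei, G2/M had the smallest camera p at the preset correlation. It had a median log2 fold change of 0.78, with 25 of 25 members above 0 and ANLN (0.78 ± 0.16 SE), KIF20B (0.65 ± 0.15 SE), MKI67 and CCNA2 (1.09 ± 0.32 SE) leading by p. camera placed it higher (adjusted p = 5.57e-10, and adjusted p = 0.781 with an estimated correlation), 0 members passed over all genes and 18 passed when adjusted over the list alone. The G1/S and S list had a median of 0.48 (adjusted p = 0.00223, and 0.781 with an estimated correlation), led by UHRF1 (0.84 ± 0.25 SE), RRM2 (1.11 ± 0.35 SE), CLSPN (0.68 ± 0.22 SE) and MCM7 (0.59 ± 0.19 SE). Without MGHS 3 the G1/S and S list no longer passed (highest adjusted p = 0.110 over the 6 fits without 1 animal), while the G2/M list passed in 6 of 6. Summed nuclei mix expression with the shares of the layers, and cycling nuclei had a higher mean share in MGHS. Cluster 9, a granular-like cluster, gave 56, 29 and 103 nuclei to the sums of MGNS 1 to 3 and 521, 701 and 245 to those of MGHS 1 to 3.

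The NF-kB and antigen presentation lists lay lower by camera in all keratinocyte-like nuclei. The list of cytokines, Toll-like receptors and NF-kB had a median of -0.75, and its leading members were the inflammatory caspase CASP1 (-2.10 ± 0.27 SE), the NF-kB inhibitor TNFAIP3 (-1.72 ± 0.29 SE), the peptidoglycan sensor NOD2 (-1.34 ± 0.25 SE) and the NF-kB subunit RELB (-1.35 ± 0.30 SE). camera placed it lower (adjusted p = 1.18e-06, and adjusted p = 0.53 with an estimated correlation), with 0 members over all genes and 9 lower adjusted over the list alone, and it passed without each of the 6 animals. The antigen presentation list had a median of -1.04 with CIITA (-1.24 ± 0.41 SE), TAPBP (-0.78 ± 0.27 SE), TAP1 (-1.56 ± 0.59 SE) and PSMB8 (-1.57 ± 0.68 SE) leading (adjusted p = 0.00223, and 0.781 with an estimated correlation). Without MGNS 2 it did not pass (adjusted p = 0.131). T or NK markers lay lower in the same sums (median -1.02, adjusted p = 1.51e-07, and 0.446 with an estimated correlation). The interferon response list had a median of -0.12 (adjusted p = 0.262), although ISG20 (-2.41 ± 0.83 SE), IFIT3 (-2.45 ± 1.14 SE), IFIT1 (-2.48 ± 1.35 SE) and IRF1 (-0.91 ± 0.51 SE) led downward. Without MGNS 2 the IFIT1 value was 0.26 and that of IFIT3 -0.42. ISG20 ranged from -2.88 to -0.97 over its alternatives.

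The antioxidant and matrix lists lay higher by camera in all keratinocyte-like nuclei. The list of xenobiotic, glutathione and antioxidant genes had a median of 0.59, with GPX1, the glutamate-cysteine ligase subunit GCLM (1.195 ± 0.21 SE) and the haem oxygenase HMOX1 (3.77 ± 0.88 SE) higher and the cystine transporter SLC7A11 lower (-3.86 ± 0.90 SE). camera passed it (adjusted p = 0.00223, and 0.781 with an estimated correlation), with 0 members over all genes and 9 higher and 3 lower adjusted over the list alone. The extracellular matrix list had a median of 0.73 with COL3A1 (1.53 ± 0.32 SE), COL5A2 (1.199 ± 0.25 SE), COL1A1 (1.52 ± 0.37 SE) and COL1A2 (1.45 ± 0.37 SE) leading (adjusted p = 1.2e-05, and 0.781 with an estimated correlation). Neither list passed without MGHS 3 (adjusted p = 0.156 and 0.0532). Fibroblast markers lay higher in the same sums (median 0.82, adjusted p = 0.000427, and 0.446 with an estimated correlation). Most of these markers, among them COL3A1, COL5A2, COL1A1 and COL1A2, are also in the matrix list, so the 2 results are not separate. Ribosomal proteins had a median of 0.36 (adjusted p = 0.00223, and 0.837 with an estimated correlation), led by RPL9 (0.51 ± 0.36 SE), and oxidative phosphorylation genes 0.27 (adjusted p = 0.0305, and 0.837 with an estimated correlation), led by NDUFB6 (0.59 ± 0.29 SE). These 2 lists passed in 3 of 6 fits without 1 animal and not without MGNS 2, MGHS 2 or MGHS 3 (highest adjusted p = 0.505 and 0.447). In all, camera passed 8 of 30 lists, 0 of them with an estimated correlation, with 15 without MGNS 1 and 4 without MGHS 3.

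Transport and fuel lists did not pass in all keratinocyte-like nuclei. Short-chain fatty acid and bicarbonate transport had a median of 0.13 (camera adjusted p = 0.204), with SLC9A3, CA1 (1.39 ± 0.45 SE) and SLC9A2 (1.21 ± 0.44 SE) upward and SLC26A9 (-2.09 ± 0.61 SE) downward. Ketogenesis and ketone use had 0.45 (adjusted p = 0.127), with ACAT1 (0.69 ± 0.23 SE) and ACAT2 (0.69 ± 0.31 SE) upward and OXCT1 (-1.58 ± 0.56 SE) downward. Ion, urea and water transport had a median of 0.02 and a mean of -0.04 (adjusted p = 0.606), with SCNN1B (-1.55 ± 0.30 SE), KCNK1 (-0.84 ± 0.22 SE) and ATP1B1 (-0.68 ± 0.19 SE) downward and AQP5 (1.92 ± 0.63 SE) upward. Glycolysis had -0.05 (adjusted p = 0.127), with HK2 (-3.61 ± 0.86 SE), PFKFB3 (-1.51 ± 0.39 SE), SLC2A1 (-0.99 ± 0.23 SE) and SLC2A3 (-1.18 ± 0.30 SE) the 4 members lower when adjusted over the list alone, and 0 over all genes. Over the alternatives HK2 ranged from -4.06 to -2.08 and OXCT1 from -1.97 to -0.78. Fatty acid oxidation and PPAR targets had -0.08 (adjusted p = 0.298), with PDK4 (-1.14 ± 0.20 SE), ACSL1 and ACSL4 (-0.89 ± 0.20 SE) lower over the list alone and 0 over all genes.

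The remaining synthesis, barrier and signalling lists did not pass by camera in all keratinocyte-like nuclei either. Cholesterol synthesis had a median of -0.12 (adjusted p = 0.508), fatty acid and ceramide synthesis -0.23 (adjusted p = 0.200, with CERS3 at -3.11 ± 0.87 SE), the citrate cycle 0.06 (adjusted p = 0.673) and mitochondrial genome transcripts 0.10 (adjusted p = 0.263). CERS3 ranged from -3.79 to -1.76 over its alternatives. Tight junction genes had -0.29 (adjusted p = 0.465, with CLDN4 at 0.96 ± 0.26 SE), desmosome and adherens junction genes -0.28 (adjusted p = 0.0909, with CDH1 at -0.90 ± 0.27 SE) and hemidesmosome and basement membrane genes 0.25 (adjusted p = 0.262). The cornified envelope list had a median of -0.01 and a mean of 0.07 (adjusted p = 0.188), while KLK12 (1.64 ± 0.29 SE), CSTA (1.53 ± 0.28 SE), ALOXE3 (2.62 ± 0.62 SE) and KLK8 (2.93 ± 0.75 SE) were among 5 members higher over the list alone and 0 passed over all genes. Stress keratins and wound response had -0.33 (adjusted p = 0.108), immediate early genes 0.02 (adjusted p = 0.623, 4 higher over the list alone and 0 over all genes), heat shock and protein folding -0.19 (adjusted p = 0.0874) and hypoxia 0.06 (adjusted p = 0.758). IGF and growth factor signalling had a median of -0.01 and a mean of 0.12 (adjusted p = 0.758), and Wnt and Notch signalling -0.02 and 0.07 (adjusted p = 0.989). Retinoid and vitamin D genes had 0.21 (adjusted p = 0.298) and circadian clock genes -0.18 (adjusted p = 0.204), and the fatty acid receptor list had 2 tested members, HCAR2 (-1.15 ± 0.55 SE) and FFAR4 (-0.24 ± 0.26 SE), too few to test.

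Within basal-like nuclei, the lowest keratinocyte layer, 2 genes passed. SLC28A3, a concentrative nucleoside transporter, fell by 2.23 ± 0.16 SE, from 65.0 ± 8.11 to 13.8 ± 0.433 CPM (edgeR adjusted p = 0.0106). SELENOW, which encodes selenoprotein W, rose by 1.70 ± 0.16 SE, from 51.8 ± 5.20 to 168 ± 22.8 CPM (adjusted p = 0.0458). GPX1 (2.88 ± 0.30 SE, adjusted p = 0.0591) and IGFBP5 (2.05 ± 0.24 SE, adjusted p = 0.0843) fell short, and for all 4 genes the groups did not overlap. edgeR called 2 of 14131 genes, DESeq2 442 and limma-voom 60, and 2209 had an unadjusted p under 0.05. For 23.7% of genes the groups did not overlap, where chance gives 10% on average. SLC28A3 passed in 15 of 18 alternatives and SELENOW in 10, and the count was 8 without MGHS 2, 3 without MGHS 3, 1 without MGNS 1 and 0 without MGNS 3 or MGHS 1. SLC28A3 was not called without MGNS 3 or MGHS 1, and SELENOW was called in 1 of the 6 fits without an animal, that without MGHS 2.

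Basal-like nuclei had more lists past camera than any other class. The G2/M list had a median of 1.07 (adjusted p = 9e-14, and 0.374 with an estimated correlation), with 18 members higher over the list alone and 0 over all genes. Short-chain fatty acid and bicarbonate transport had 0.57 and ketogenesis and ketone use 0.55 (both adjusted p = 0.000833, and 0.374 with an estimated correlation), with 3 and 5 members higher over the list alone and 0 over all genes. The ribosomal protein list had 0.45 with 46 of 46 members above 0 (adjusted p = 7.52e-08, and 0.801 with an estimated correlation), and the tight junction list had -0.34 (adjusted p = 0.00189, and 0.374 with an estimated correlation). The interferon response list had a median of -1.25 with 0 of 29 members above 0 (adjusted p = 0.00016, and 0.801 with an estimated correlation), but 0.03 and no call without MGNS 2 (adjusted p = 0.801). camera passed 13 of 30 lists in basal-like nuclei, 8 higher and 5 lower.

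Spinous-like nuclei, the middle layer, had 3 genes past the test, 1 of which is an unnamed locus. PADI1, which converts arginine to citrulline in proteins, rose by 3.51 ± 0.23 SE, from 7.24 ± 0.685 to 82.2 ± 13.97 CPM (edgeR adjusted p = 0.00239), and passed in 18 of 18 alternatives. SLC28A3 fell by 2.54 ± 0.28 SE, from 221 ± 72.4 to 38.2 ± 6.43 CPM (adjusted p = 0.0461), and passed in 12 of 18. The groups did not overlap for these genes, nor for 18.5% of all genes, where chance gives 10% on average. edgeR called 3 of 11613 genes, DESeq2 275 and limma-voom 2, with 1486 at an unadjusted p under 0.05. The count was 12 without MGHS 3, 9 without MGNS 1 and 1 without MGNS 2 or MGHS 1, and SLC28A3 was called in 1 of the 6 fits without an animal, that without MGNS 1. The glycolysis list lay lower (median -0.37, camera adjusted p = 6.33e-05, and 0.781 with an estimated correlation), with 5 members lower over the list alone and 0 over all genes, and it passed without each of the 6 animals. camera passed 7 of 30 lists, 3 higher and 4 lower.

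Granular-like nuclei comprised clusters 3 and 9, whose proportions differed between the groups. TMPRSS2, a membrane serine protease, was the 1 gene called there (log2 fold change -6.15 ± 0.52 SE, edgeR adjusted p = 0.0263). It had 27.8 ± 8.30 CPM in MGNS and 0.394 ± 0.280 CPM in MGHS, with 105, 284 and 136 UMIs in MGNS 1 to 3 against 1, 4 and 4 in MGHS 1 to 3. The ratio of rates was 77.1, with an exact 95% interval of 40.3 to 170 that covers counting error only. Within cluster 3 the groups had 495 and 4 UMIs (ratio 126, interval 48.9 to 464), and within cluster 9 they had 30 and 5 (ratio 50.1, interval 19.2 to 165). TMPRSS2 lay under the expression minimum for named genes and was chosen after its values were seen. Its call held in 8 of 18 alternatives and, with 1 animal left out, without MGHS 3 only, ending without MGNS 1, MGNS 2, MGNS 3, MGHS 1 or MGHS 2 (highest adjusted p = 0.197). edgeR called 1 of 12548 genes, DESeq2 615 and limma-voom 50, with 2206 at an unadjusted p under 0.05, and 168 genes were called without MGHS 3. Groups lay apart for 22.5% of genes, where chance gives 10% on average.

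Granular-like lists were led by the NF-kB list. It had a median of -0.91 (camera adjusted p = 0.000167, and 0.639 with an estimated correlation), with 8 members lower over the list alone and 0 over all genes. Glycolysis had -0.36 (adjusted p = 0.0353, and 0.639 with an estimated correlation), desmosome and adherens junction genes -0.29 (adjusted p = 0.0398, and 0.639 with an estimated correlation) and hemidesmosome and basement membrane genes 0.50 (adjusted p = 0.0299, and 0.639 with an estimated correlation). Basal keratinocyte markers had 0.84 in clusters 3 and 9 together (adjusted p = 0.0198, and 0.619 with an estimated correlation) but did not pass without MGNS 1, MGHS 2 or MGHS 3 (highest adjusted p = 0.168). Many of these markers, such as COL17A1, ITGA6 and LAMB3, are also in the hemidesmosome and basement membrane list. camera passed 9 of 30 lists, but 1 without MGNS 2 or MGHS 3, the NF-kB list, which passed without each of the 6 animals. The other 3 lists named here did not pass in those fits (highest adjusted p = 0.197, 0.244 and 0.251).

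Cycling keratinocyte-like nuclei had 13 genes past the test, 7 higher and 6 lower. SELENOW rose by 1.72 ± 0.20 SE (from 76.7 ± 6.57 to 252 ± 48.7 CPM, edgeR adjusted p = 0.0150) and GPX1 by 2.86 ± 0.37 SE (from 64.7 ± 30.8 to 467 ± 144 CPM, adjusted p = 0.0377). LYPD2 rose by 2.33 ± 0.32 SE (adjusted p = 0.0377) and the keratin KRT36 by 2.36 ± 0.35 SE (adjusted p = 0.0485). SLC28A3 fell by 1.80 ± 0.26 SE (from 35.5 ± 1.27 to 9.92 ± 1.43 CPM), the polarity gene PARD3B by 1.44 ± 0.22 SE and the elastase inhibitor SERPINB1 by 1.26 ± 0.20 SE (each adjusted p = 0.0377), and the complement protease C1R by 2.25 ± 0.37 SE (adjusted p = 0.0485). The groups did not overlap for these 8 genes, nor for 20.3% of all genes, where chance gives 10% on average. edgeR called 13 of 10341 genes, DESeq2 197 and limma-voom 18, with 1476 at an unadjusted p under 0.05. SELENOW passed in 16 of 18 alternatives, GPX1 in 14, LYPD2 and SERPINB1 in 12 each, SLC28A3 in 11, PARD3B in 10 and KRT36 in 9, and C1R in 6 of 17. The count was 162 without MGNS 3, 2 without MGNS 1 or MGHS 3, and 0 without MGHS 1.

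Lists in cycling keratinocyte-like nuclei were led by matrix and ribosomal genes. The extracellular matrix list had a median of 1.44 (camera adjusted p = 5.8e-10, and 0.380 with an estimated correlation) with 6 members higher over the list alone and 0 over all genes, and the ribosomal protein list had 0.48 (adjusted p = 5.7e-11, and 0.776 with an estimated correlation). Fibroblast markers, most of which are also in the matrix list, lay higher in the same nuclei, with a median of 1.47 (adjusted p = 6.73e-10, and 0.103 with an estimated correlation). The antioxidant list had 0.71 (adjusted p = 1.41e-06, and 0.389 with an estimated correlation), with 11 members higher over the list alone and 1, GPX1, over all genes. Tight junction genes had -0.31 (adjusted p = 0.0326, and 0.380 with an estimated correlation) and were the 1 list that also passed by fry, which asks if members move one way on balance (adjusted p = 0.00972), but not by camera without MGNS 1, MGNS 3 or MGHS 2 (highest adjusted p = 0.243). camera passed 9 of 30 lists, with 14 without MGHS 3 and 5 without MGHS 2.

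Whether the group difference itself varied between neighbouring layers was tested with an interaction in limma. Between basal-like and spinous-like nuclei 0 of 11407 genes passed (1262 at an unadjusted p under 0.05, where 570 would be expected by chance, smallest adjusted p 0.0615). Between spinous-like and granular-like nuclei 0 of 10951 passed (1315 at an unadjusted p under 0.05, where 548 would be expected, smallest adjusted p 0.141). No other tool was run for this test. Without MGHS 3 the counts were 9 and 216. A call such as PADI1 in spinous-like nuclei is therefore not shown to differ from the other layers, and cluster 3, counted as granular-like, scored as high for spinous markers (mean log2 ratio 1.39) as for granular ones (1.31).

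**Figure D2:**
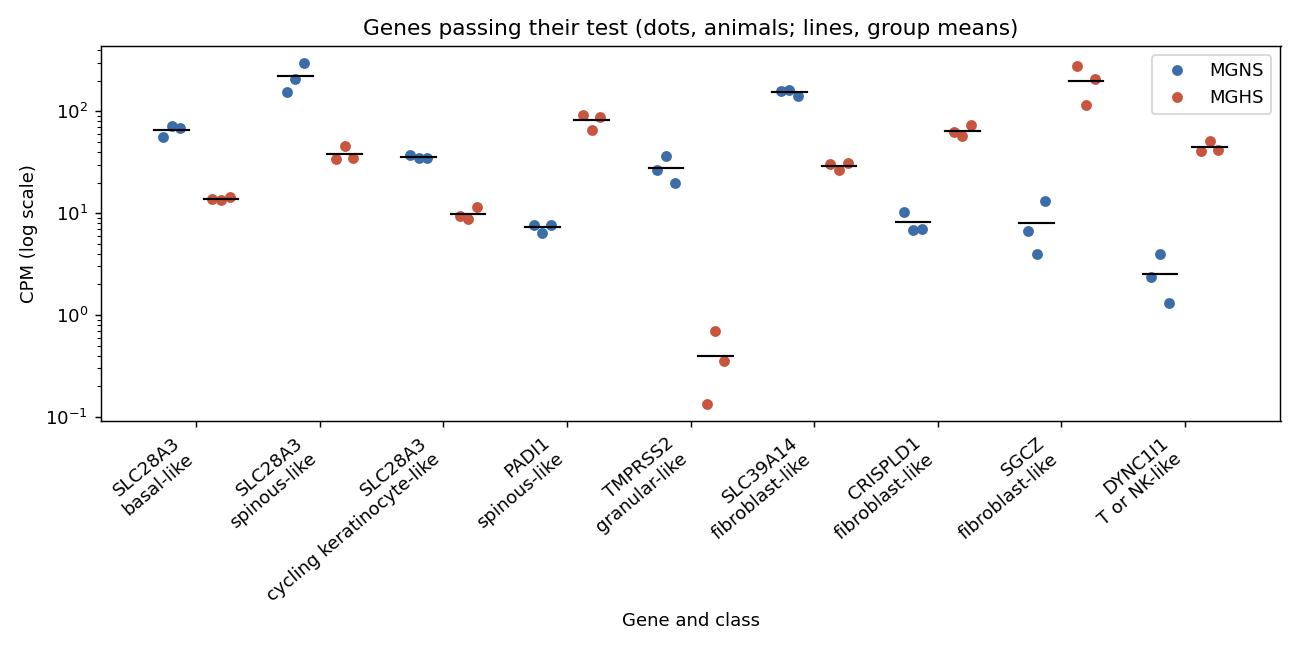
CPM on a log axis (vertical) for genes past the edgeR test in the class named on the horizontal axis, with dots for 3 MGNS and 3 MGHS animals and lines for group means. PADI1 averaged 7.24 CPM in MGNS and 82.2 in MGHS in spinous-like nuclei, and TMPRSS2 27.8 and 0.394 in granular-like nuclei.

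Fibroblast-like nuclei had 11 genes past the test, 3 higher and 8 lower, of which 4 are unnamed loci. SLC39A14, a zinc transporter, fell by 2.39 ± 0.17 SE, from 154 ± 11.6 to 29.2 ± 2.27 CPM (edgeR adjusted p = 0.00305), and the secreted protein gene CRISPLD1 rose by 2.99 ± 0.25 SE, from 8.10 ± 1.98 to 64.5 ± 7.91 CPM (adjusted p = 0.00541). Both passed in 18 of 18 alternatives. The sarcoglycan SGCZ rose by 4.61 ± 0.47 SE, from 7.94 ± 4.82 to 200 ± 81.4 CPM, while the syndecan SDC4 fell by 1.87 ± 0.21 SE, KIAA1755 by 1.85 ± 0.21 SE and RELB by 1.65 ± 0.20 SE (each adjusted p = 0.0288). LTBP2, a matrix protein, fell by 1.73 ± 0.21 SE (adjusted p = 0.0307). The groups did not overlap for these 7 genes, nor for 19.7% of all genes, where chance gives 10% on average. edgeR called 11 of 12286 genes, DESeq2 294 and limma-voom 75, with 1617 at an unadjusted p under 0.05. The count was 2 without MGHS 1, 3 without MGNS 1, MGNS 3 or MGHS 2, and 4 without MGNS 2, and RELB, LTBP2 and KIAA1755 were not called without any 1 of the 6 animals (highest adjusted p = 0.109, 0.127 and 0.101). SGCZ passed in 14 of 18 alternatives and SDC4 in 12, SGCZ not without MGNS 1, MGNS 2, MGHS 1 or MGHS 3 (highest adjusted p = 0.0890) and SDC4 only without MGHS 3 among these 6 fits (highest 0.127). Over all alternatives the log2 fold changes lay at 4.30 to 5.22 for SGCZ, -2.02 to -1.70 for SDC4, -1.78 to -1.57 for RELB, -1.80 to -1.19 for LTBP2 and -1.97 to -1.77 for KIAA1755.

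In fibroblast-like nuclei the NF-kB and antigen presentation lists lay lower by camera, as did T or NK markers (median -0.77, adjusted p = 0.00119, and 0.504 with an estimated correlation). The NF-kB list had a median of -0.83 (camera adjusted p = 2.29e-12, adjusted p = 0.0761 with an estimated correlation, fry adjusted p = 0.0427), with 12 members lower over the list alone and 1, RELB, over all genes. Antigen presentation had -0.64 (adjusted p = 0.000147, and 0.755 with an estimated correlation) with 4 members lower over the list alone and 0 over all genes. The G2/M list had 0.92 (adjusted p = 0.000203, and 0.762 with an estimated correlation) and the extracellular matrix list 0.26 (adjusted p = 0.000203, and 0.755 with an estimated correlation), with 2 and 6 members higher over the list alone and 0 over all genes. These 4 lists passed without each of the 6 animals. camera passed 6 of 30 lists, with 11 without MGNS 1 and 10 without MGHS 2 or MGHS 3.

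In T or NK-like nuclei, made of clusters 2, 4 and 8 in proportions that differed between the groups, 1 gene passed. DYNC1I1, a dynein intermediate chain, rose by 4.02 ± 0.33 SE, from 2.55 ± 1.34 to 44.7 ± 5.89 CPM, with every MGHS animal above every MGNS animal (edgeR adjusted p = 0.00536). It passed in 17 of 18 alternatives, the exception being the fit without MGNS 1 (highest adjusted p = 0.0523). edgeR called 1 of 11781 genes, DESeq2 84 and limma-voom 1, with 835 at an unadjusted p under 0.05, and 2 without MGNS 2. Of all genes, 12.2% had groups apart, where chance gives 10% on average. The NF-kB list had a median of -0.41 (camera adjusted p = 2.14e-05, and 0.167 with an estimated correlation), antigen presentation -0.28 (adjusted p = 0.00223, and 0.765 with an estimated correlation), and both passed without each of the 6 animals. Cholesterol synthesis had 0.36 (adjusted p = 0.00656, and 0.925 with an estimated correlation) but not without MGNS 2 or MGHS 3 (highest adjusted p = 0.492). camera passed 10 of 30 lists, with 5 without MGNS 2 or MGHS 3.

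Blood endothelial-like nuclei had 7 genes past the test, 4 higher and 3 lower, each with an edgeR adjusted p of 0.0471. SELENOW rose by 1.34 ± 0.19 SE, from 62.9 ± 10.7 to 160 ± 18.6 CPM. KRT36 rose by 1.80 ± 0.22 SE, LYPD2 by 1.81 ± 0.24 SE and the carbonic anhydrase CA1 by 2.03 ± 0.27 SE, and these 3 stood at 14.2%, 14.7% and 14.7% of their level in keratinocyte-like nuclei. The phospholipase PLCB4 fell by 1.12 ± 0.15 SE, from 557 ± 49.4 to 256 ± 9.77 CPM, PARP8 by 1.06 ± 0.16 SE and the ceramidase ACER2 by 1.21 ± 0.18 SE. The groups did not overlap for these 7 genes, nor for 15.7% of all genes, where chance gives 10% on average. edgeR called 7 of 9520 genes, DESeq2 68 and limma-voom 8, with 931 at an unadjusted p under 0.05. The count was 25 without MGNS 3, 1 without MGNS 1 and 0 without MGNS 2, MGHS 1, MGHS 2 or MGHS 3. The log2 fold changes kept their direction over all alternatives, at 1.23 to 1.49 for SELENOW, 1.66 to 2.09 for KRT36, 1.65 to 1.93 for LYPD2, 1.80 to 2.45 for CA1, -1.21 to -1.09 for PLCB4, -1.13 to -0.87 for PARP8 and -1.36 to -1.13 for ACER2. Of 18 alternatives KRT36 and LYPD2 passed in 12 each, PLCB4 in 11, CA1 and SELENOW in 10 each, ACER2 in 9 and PARP8 in 8, and with doublets kept 0 of the 7 passed.

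Blood endothelial-like lists were led by the NF-kB list, with a median of -0.47 (camera adjusted p = 1.98e-08, and 0.607 with an estimated correlation) and 7 members lower over the list alone and 0 over all genes. Oxidative phosphorylation had 0.50 (adjusted p = 4.38e-07, and 0.607 with an estimated correlation). Both passed without each of the 6 animals. Hypoxia genes had -0.24 (adjusted p = 0.0186, and 0.661 with an estimated correlation) and IGF and growth factor signalling -0.19 (adjusted p = 0.00401, and 0.607 with an estimated correlation), but hypoxia not without MGNS 2, MGNS 3 or MGHS 3 (highest adjusted p = 0.303) and IGF signalling not without MGNS 3 (adjusted p = 0.113). camera passed 11 of 29 lists, with 6 without MGNS 2 and 7 without MGHS 3.

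In 5 other classes edgeR called 0 genes. Smooth muscle or pericyte-like nuclei had 1526 of 11544 genes at an unadjusted p under 0.05, DESeq2 called 240 and limma-voom 20, and edgeR called 26 without MGHS 3, 7 without MGNS 1 or MGHS 2 and 1 without MGHS 1. Macrophage or dendritic-like nuclei had 744 of 11669 (DESeq2 43, limma-voom 0), with 1 without MGNS 1 or MGNS 2, and neutrophil-like nuclei 278 of 4248 (DESeq2 2, limma-voom 0). B or plasma-like nuclei had 576 of 6629 (DESeq2 24, limma-voom 10), with 9 without MGHS 2, 4 without MGNS 3 and 2 without MGNS 2, and lymphatic endothelial-like nuclei 598 of 7347 (DESeq2 47, limma-voom 0), with 29 without MGNS 3. GPX1 had 1.82 ± 0.31 SE in lymphatic endothelial-like (adjusted p = 0.128), 1.72 ± 0.41 SE in neutrophil-like (adjusted p = 0.355), 1.26 ± 0.34 SE in smooth muscle or pericyte-like (adjusted p = 0.193), 1.11 ± 0.25 SE in macrophage or dendritic-like (adjusted p = 0.578) and 1.11 ± 0.38 SE in B or plasma-like nuclei (adjusted p = 0.483), with the groups apart in all 5. All nuclei summed had 3742 of 18829 genes at an unadjusted p under 0.05, and edgeR called 0, or 63 without MGHS 3, DESeq2 1431 and limma-voom 280.

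In cluster 0, unnamed but with the keratinocyte genes KRT36, KRTDAP, KRT6A and IVL among its leading genes, and to which MGHS 3 gave most nuclei, 19 genes passed, 14 higher and 5 lower. GPX1 rose by 2.34 ± 0.31 SE, from 64.9 ± 29.97 to 328 ± 56.8 CPM (edgeR adjusted p = 0.0293), and SERPINB1 fell by 1.35 ± 0.22 SE (adjusted p = 0.0419). GRIP1 rose by 2.28 ± 0.39 SE, SELENOW by 1.62 ± 0.28 SE and the sterol reductase TM7SF2 by 2.03 ± 0.35 SE (each adjusted p = 0.0443). JPT1 rose by 1.48 ± 0.27 SE (adjusted p = 0.0465) and CSRP2 by 2.04 ± 0.35 SE (adjusted p = 0.0492), while ASTN2 fell by 1.68 ± 0.30 SE and the pyruvate dehydrogenase kinase PDK4 by 1.71 ± 0.30 SE (each adjusted p = 0.0448). Groups lay apart for these 9 genes and for 17.8% of all genes, where chance gives 10% on average. edgeR called 19 of 8080 genes, DESeq2 70 and limma-voom 19, with 915 at an unadjusted p under 0.05. The count was 48 without MGNS 3, 1 without MGNS 1 and 0 without MGNS 2, MGHS 1 or MGHS 2, and GPX1 passed in 15 of 18 alternatives, SERPINB1 in 11, SELENOW, PDK4 and JPT1 in 8, 8 and 6, and CSRP2 in 5. Of 17 alternatives each, TM7SF2 passed in 9, ASTN2 in 8 and GRIP1 in 6. The log2 fold change of GRIP1 ranged from 0.42 to 2.73 over these.

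SELENOW and GPX1 lay higher together over the 13 single classes. SELENOW was higher in 12 of the 12 classes where it was tested, by 2.39-fold to 3.80-fold with a median of 3.02-fold. GPX1 was higher in 13 of 13, by 2.15-fold to 7.37-fold with a median of 3.08-fold. In each of these classes every MGHS animal lay above every MGNS animal for both genes. SELENOW passed its edgeR test in basal-like, cycling keratinocyte-like, blood endothelial-like and cluster 0 nuclei, and GPX1 in cycling keratinocyte-like and cluster 0 nuclei. The classes share animals and are not independent. Both genes were singled out after their values were seen.

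**Figure D3:**
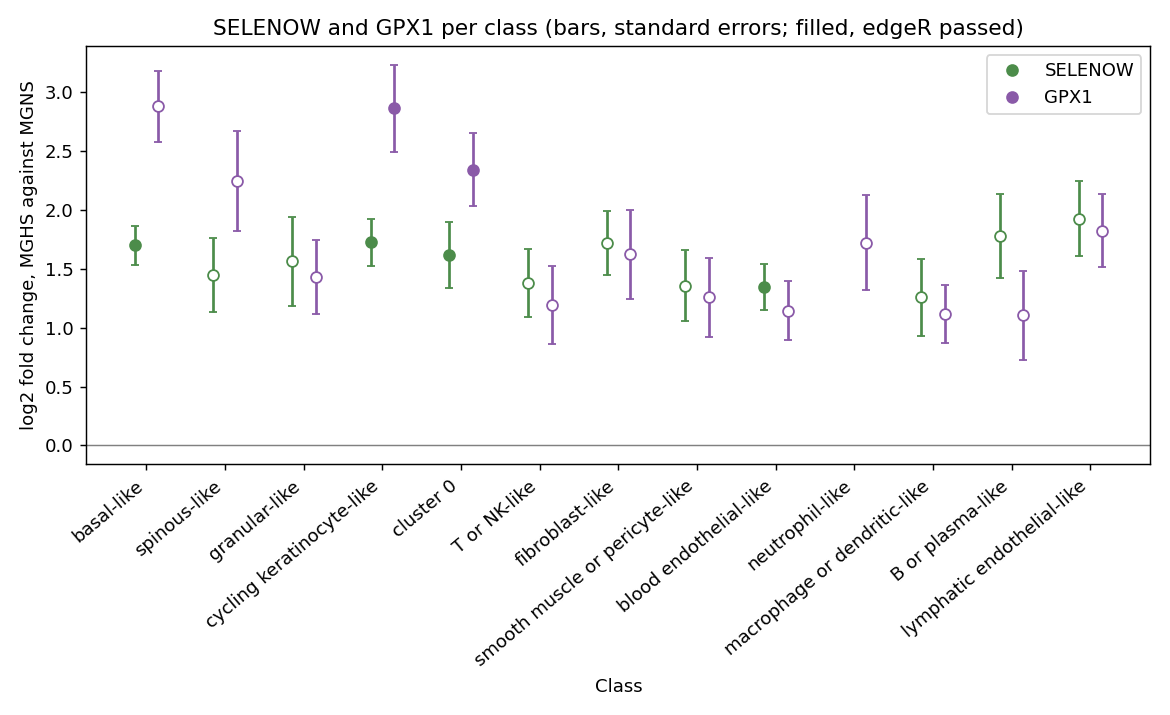
log2 fold change, MGHS against MGNS (vertical axis), of SELENOW and GPX1 in each single class (horizontal axis), from 3 animals per group, with bars for standard errors and filled points where edgeR passed. GPX1 lay between 1.11 in B or plasma-like and 2.88 in basal-like nuclei.

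Across the same 13 classes, the NF-kB list was lower by camera in 11, antigen presentation in 11 and the interferon response in 6. Extracellular matrix genes were higher in 10 classes, oxidative phosphorylation and the antioxidant list in 9 each, and ribosomal proteins in 5. With an estimated correlation 0 of these calls held in any class. Marker lists of other cell types shifted as well. T or NK markers were lower by camera in 12 of 13 classes, all but T or NK-like, with a median below 0 in all 13, and fibroblast markers higher in 9, and with an estimated correlation both passed in 0. Most fibroblast markers are also members of the extracellular matrix list. Spinous keratinocyte markers were higher in 9 of 13 and basal keratinocyte markers in 7 of 13, and in 0 with an estimated correlation. Neutrophil-like nuclei were the 1 class with an NF-kB median above 0.

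**Figure D4:**
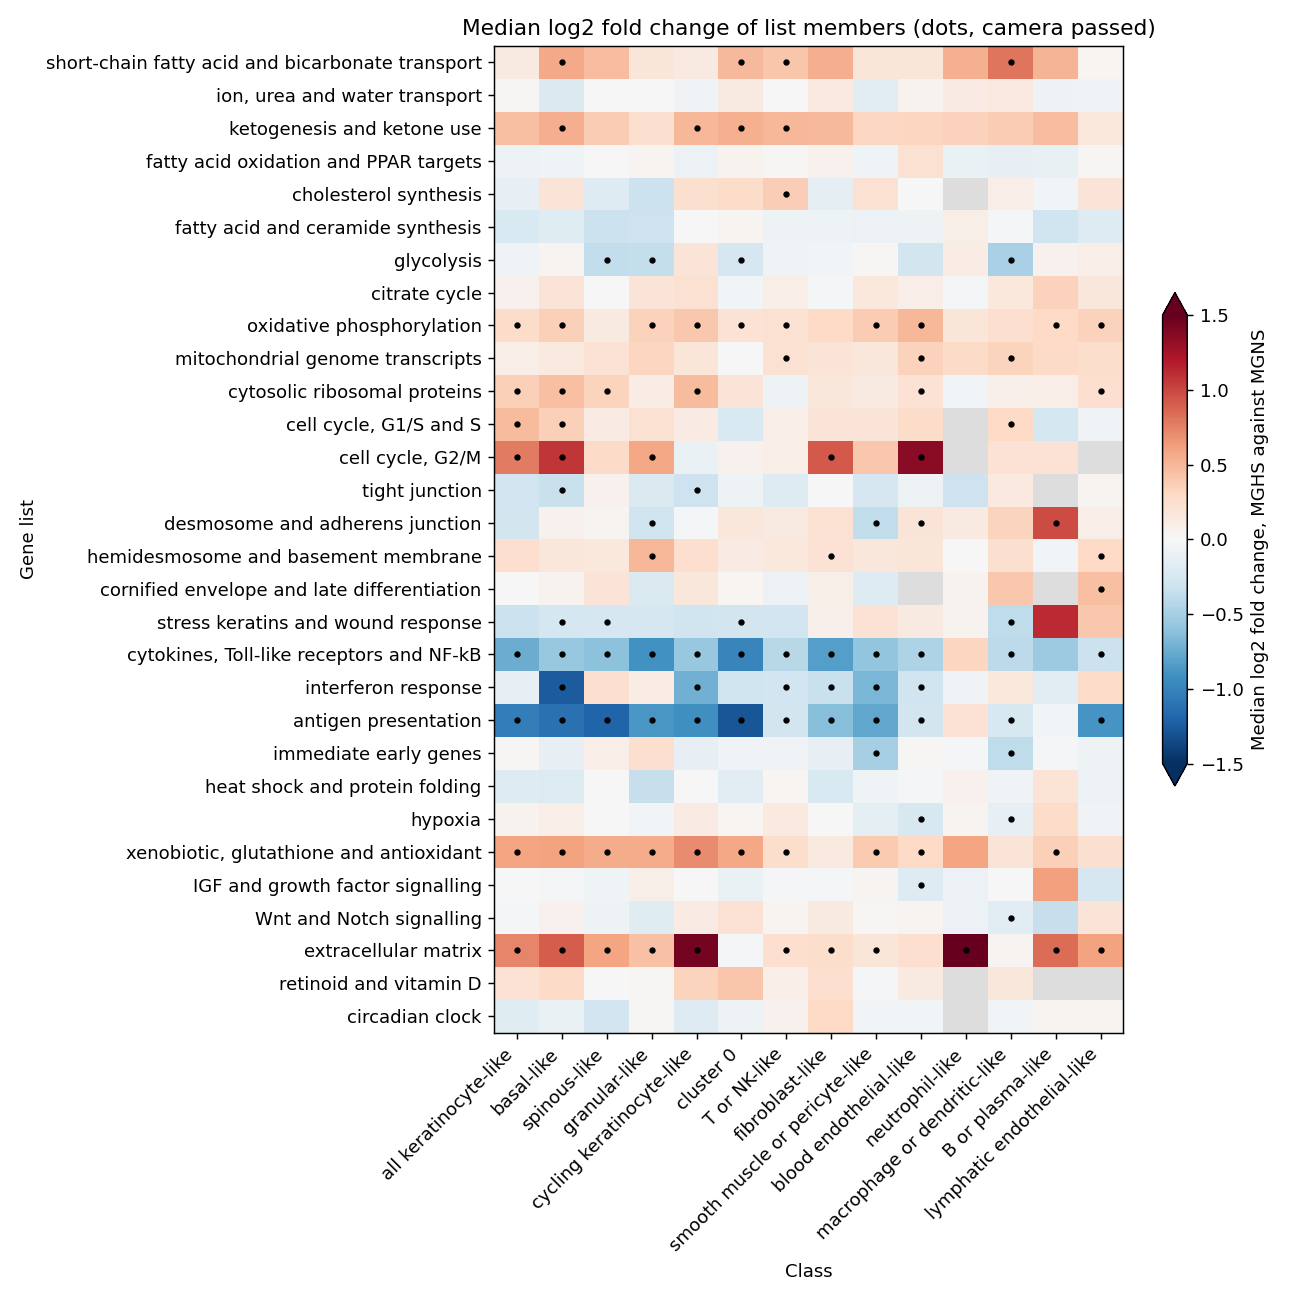
Median log2 fold change of each gene list (rows of the grid) in each class (columns), MGHS against MGNS with 3 animals each, in colour, with dots where camera passed at its preset correlation and grey where too few members were tested. The NF-kB list was lower by camera in 11 of 13 single classes and with an estimated correlation in 0.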

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

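The shares that leave cluster 0 out of the total, with or without MGHS 3, were the tests in this part chosen only after the result was seen. Of 2977 refits of the named genes, 2660 kept their direction and their side of the adjusted p of 0.05, 250 kept direction and lost the call, 64 kept direction and gained one, and 3 changed sign. All 250 losses fell on the 37 named genes that edgeR called, which passed in 412 of their 662 refits. With RLE size factors no count of genes moved by more than 1.5 times, and the genes called in cluster 0, basal-like, T or NK-like, granular-like, fibroblast-like, spinous-like, blood endothelial-like and cycling keratinocyte-like nuclei were all called again. DYNC1I1 in T or NK-like nuclei passed in 17 of 18 alternatives, and PADI1 in spinous-like, SLC39A14 and CRISPLD1 in fibroblast-like nuclei in 18 of 18.

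DESeq2 called more genes than edgeR in every class, and the cause was not tested. It called 1024 in all keratinocyte-like nuclei (edgeR 0), 1431 in all nuclei (0), 442 in basal-like (2), 275 in spinous-like (3), 615 in granular-like (1) and 197 in cycling keratinocyte-like nuclei (13). It called 294 in fibroblast-like (11), 84 in T or NK-like (1), 68 in blood endothelial-like (7), 70 in cluster 0 (19), 240 in smooth muscle or pericyte-like (0), 43 in macrophage or dendritic-like (0), 24 in B or plasma-like (0), 47 in lymphatic endothelial-like (0) and 2 in neutrophil-like nuclei (0). limma-voom with quality weights called 280 in all nuclei, 60 in basal-like, 50 in granular-like, 75 in fibroblast-like, 20 in smooth muscle or pericyte-like and 10 in B or plasma-like nuclei, and the cause was not tested. It put a mitochondrial transcript (CYTB, all keratinocyte-like) at -0.0702 where edgeR had 0.28, neither past its test, and the cause was not tested.

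Without a filter on low counts edgeR called 14 genes in all keratinocyte-like nuclei, 16 in all nuclei, 287 in cluster 0, 32 in basal-like, 104 in T or NK-like, 103 in granular-like, 188 in fibroblast-like, 168 in spinous-like, 211 in smooth muscle or pericyte-like, 321 in blood endothelial-like, 586 in cycling keratinocyte-like, 23 in neutrophil-like, 8 in macrophage or dendritic-like, 262 in B or plasma-like and 187 in lymphatic endothelial-like nuclei. Every gene called with the filter was called again in cluster 0, basal-like, fibroblast-like, spinous-like, blood endothelial-like and cycling keratinocyte-like nuclei, and the cause of the added calls was not tested. With a minimum count of 50 the counts were 5 in cluster 0 and 1 in cycling keratinocyte-like nuclei, where 7 and 3 of the called genes were no longer tested, and 2 genes passed for the difference between basal-like and spinous-like nuclei where 0 had passed by limma, and the cause was not tested.

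All lists lost their camera call with an estimated correlation, which gave 0 in each of the 15 fits: all keratinocyte-like, all nuclei, cluster 0, basal-like, T or NK-like, granular-like, fibroblast-like, spinous-like, smooth muscle or pericyte-like, blood endothelial-like, cycling keratinocyte-like, neutrophil-like, macrophage or dendritic-like, B or plasma-like and lymphatic endothelial-like nuclei. fry gave 1 list in fibroblast-like and 1 in cycling keratinocyte-like nuclei and 0 in the other 13, and the cause was not tested. An estimated correlation widens the error where members of a list move together, which is how that alternative differs from the preset correlation of 0.01.

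Changes to the nuclei and clusters moved the smaller counts, and the cause was not tested. With doublets kept, edgeR called 12 genes in all nuclei, 1 in basal-like, 0 in granular-like, 0 in blood endothelial-like (7 with doublets removed), 1 in B or plasma-like and 9 in lymphatic endothelial-like nuclei. With at least 600 genes per nucleus it called 4 in cluster 0, 4 in blood endothelial-like and 8 in cycling keratinocyte-like nuclei. Leiden resolution 0.5 gave 1 in basal-like, 0 in granular-like, 24 in fibroblast-like, 6 in spinous-like, 11 in blood endothelial-like and 7 in cycling keratinocyte-like nuclei, and Leiden resolution 1.2 gave 1 in all keratinocyte-like, 0 in basal-like, 0 in granular-like and 5 in spinous-like nuclei. Ordinary nearest neighbours gave 2 in cluster 0, 5 in basal-like, 7 in spinous-like and 1 in cycling keratinocyte-like nuclei. In basal-like nuclei both called genes, SLC28A3 and SELENOW, lost their call at resolution 1.2, and of the 13 in cycling keratinocyte-like nuclei 1 was shared with ordinary nearest neighbours.

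Lowering depth by random thinning moved counts both ways, and depth was not isolated as a cause. Thinned to the smallest library, where counts are fewer by construction, edgeR called 7 genes in cluster 0, all of them among its 19, 0 in granular-like, 5 in spinous-like and 2 in blood endothelial-like nuclei. The gain in spinous-like nuclei runs against a loss of depth, and the cause was not tested.

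The replicate number as a block is a hint from numbering, not from the design. Same-numbered animals had correlations of -0.0172, -0.0609 and -0.00112 over all nuclei and -0.125, -0.0643 and 0.0155 over all keratinocyte-like nuclei, so not every animal correlated best with its own number and the numbers were not taken as pairs. With the replicate block edgeR called 15 genes in basal-like, 2 in T or NK-like, 0 in granular-like, 4 in fibroblast-like, 8 in spinous-like, 1 in smooth muscle or pericyte-like, 13 in blood endothelial-like, 135 in cycling keratinocyte-like and 55 in lymphatic endothelial-like nuclei. Lists by camera with the block numbered 11 in spinous-like and 2 in neutrophil-like nuclei, and 1 gene passed for the difference between basal-like and spinous-like nuclei. Lists in granular-like nuclei went from 9 to 6. Counts of genes and lists in the other classes moved by less than 1.5 times, and the cause was not tested.

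No share can pass by permutation of 3 animals against 3. edgeR on nuclei counts called B or plasma-like nuclei (-2.37), cluster 19 (-2.12) and glia-like nuclei (-1.64), and with the replicate block B or plasma-like nuclei (-2.50, adjusted p = 0.00323) and cluster 19 (-2.18, adjusted p = 0.00562) but not glia-like nuclei (adjusted p = 0.0530). For the share, basal-like, the log2 ratio of -0.0131 changed sign to 0.0205 with at least 600 genes, 0.0237 at Leiden resolution 0.5, 0.0305 at Leiden resolution 1.2, 0.145 with cluster 0 left out and 0.195 with cluster 0 and the MGHS 3 library left out, all far within the spread between animals, and the cause was not tested. Median UMIs per nucleus changed sign to 0.0189 with at least 600 genes, from -0.098, and the cause was not tested.

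Leaving out 1 animal at a time, with the other group kept whole, moved most counts. Genes called by edgeR ranged from 0 to 180 in all keratinocyte-like, 0 to 63 in all nuclei, 0 to 48 in cluster 0, 0 to 8 in basal-like, 0 to 2 in T or NK-like, 0 to 168 in granular-like, 2 to 8 in fibroblast-like, 1 to 12 in spinous-like, 0 to 26 in smooth muscle or pericyte-like, 0 to 25 in blood endothelial-like, 0 to 162 in cycling keratinocyte-like, 0 to 1 in macrophage or dendritic-like, 0 to 9 in B or plasma-like and 0 to 29 in lymphatic endothelial-like nuclei. The highest counts came without MGHS 3 in all keratinocyte-like, all nuclei, granular-like, spinous-like, fibroblast-like and smooth muscle or pericyte-like nuclei, and without MGNS 3 in cluster 0, blood endothelial-like, cycling keratinocyte-like and lymphatic endothelial-like nuclei. Genes past the difference between classes ranged from 0 to 9 for basal-like against spinous-like and 0 to 216 for spinous-like against granular-like nuclei, both highest without MGHS 3, and the cause was not tested.

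Lists by camera without 1 animal ranged from 4 to 15 in all keratinocyte-like, 5 to 10 in cluster 0, 5 to 10 in T or NK-like, 1 to 10 in granular-like, 5 to 11 in fibroblast-like, 6 to 14 in blood endothelial-like, 5 to 14 in cycling keratinocyte-like, 1 to 5 in neutrophil-like, 6 to 14 in macrophage or dendritic-like, 0 to 13 in B or plasma-like and 4 to 8 in lymphatic endothelial-like nuclei. The lowest of these came without MGHS 3 in all keratinocyte-like and B or plasma-like nuclei, and the highest in B or plasma-like nuclei without MGHS 2, and the cause was not tested.

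Some differences changed sign without 1 animal, none of them past a test, and the cause was not tested. The share, basal-like, ranged from -0.32 to 0.16, the share, fibroblast-like, from -0.0684 to 0.58 (changing sign without MGNS 2) and the share, lymphatic endothelial-like, from -0.18 to 0.28 (without MGNS 2 or MGHS 2). Total UMIs ranged from -0.20 to 0.26 and median UMIs per nucleus from -0.23 to 0.0401. In all keratinocyte-like nuclei CYTB ranged from -0.14 to 0.61 and the interferon-induced IFIT1 from -4.08 to 0.26, against 0.28 and -2.48 with all 6 animals, and both changed sign without MGNS 2.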

Other observations

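The ratio of ribosomal protein to SELENOW changes and the splits for genes changed were the tests in this part chosen only after the result was seen. Each of the 3 patterns below was itself noticed in these data.

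SELENOW and GPX1 lay higher in MGHS in 12 of 12 and 13 of 13 single classes where they were tested. For SELENOW in T or NK-like, fibroblast-like and blood endothelial-like nuclei, an expected difference was computed for free RNA with the transcript make-up of keratinocyte-like nuclei. The observed difference was 6.95, 5.53 and 10.6 times that (median 6.95), which argues against free RNA of that make-up as the cause. Free RNA of another make-up or from other cell types was not tested, nor were GPX1 and the other classes. For more cytoplasmic RNA carried over in MGHS, the ribosomal protein list changed by 0.11 of the SELENOW change (median of 12 classes). This argues only against a carry-over that raises both alike. Oxidative phosphorylation lay higher by camera in 9 of 13 classes, and mitochondrial genome transcripts had a median above 0 in 13 of 13. Carry-over that differs between transcripts therefore stays open. A response of selenoprotein genes in general stays open. The other 19 had a median log2 fold change of 0.14 in all keratinocyte-like nuclei, below the bound of 0.2 set in advance but by less than its error of 0.19. That error comes from the spread between genes, taken as independent, and not between animals. In single classes the median of the other genes ranged from -0.15 in neutrophil-like (5 tested) to 0.40 in cycling keratinocyte-like nuclei (15 tested). In B or plasma-like nuclei 12 of 12 lay above 0, and in fibroblast-like nuclei 8 of 18. Among the 19 in all keratinocyte-like nuclei, GPX2 (1.53 ± 0.73 SE), GPX4 (1.31 ± 0.45 SE), SELENOH (1.44 ± 0.41 SE) and MSRB1 (0.68 ± 0.30 SE) lay above 0. SELENOI (-0.65 ± 0.20 SE) and SELENON (-0.57 ± 0.30 SE) lay below, and all of these were singled out after their values were seen. A difference between the MGNS and MGHS treatments stays open as untested.

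The NF-kB list lay lower by camera in MGHS in all keratinocyte-like nuclei, where fewer immune cells in MGHS could leave less free immune RNA. Of its 29 tested members, 6 were higher in keratinocyte-like nuclei than in each immune class, and these had a median log2 fold change of -0.26, with 4 of 6 lower and an interquartile range of -0.42 to 0.36. The other members had a median of -0.87. The value for the 6 lies between the bounds set in advance, above -0.2 for free RNA and at or below -0.4 against it, so free immune RNA and a change inside keratinocytes cannot be told apart with 6 members. A difference between the MGNS and MGHS treatments stays open as untested.

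KRT36, LYPD2 and CA1 rose in blood endothelial-like nuclei. Free RNA from keratinocytes is a candidate explanation, since these genes stood there at 14.2%, 14.7% and 14.7% of their keratinocyte level, close to keratinocyte marker genes in the same nuclei (median log2 ratio 0.53, within the range of -1 to 1 set in advance). These calls in blood endothelial-like nuclei may therefore describe keratinocytes. A change inside endothelial cells, and a difference between the treatments there, stay open as untested.

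The 6 animals can be split 3 against 3 in 10 ways, so no share under 0.05 can be reached. For genes by edgeR, the real split called 19 in cluster 0 (highest other 1), 2 in basal-like (0), 1 in granular-like (0), 3 in spinous-like (1), 13 in cycling keratinocyte-like (1), 11 in fibroblast-like (0) and 7 in blood endothelial-like nuclei (1), and 1 of 10 splits, the real one, gave as many in each. In T or NK-like nuclei it called 1 (highest other 2), and 4 of 10 splits gave as many. The real split called 0 genes, so that 10 of 10 gave as many, in all keratinocyte-like (highest other 1), all nuclei (0), smooth muscle or pericyte-like (1), macrophage or dendritic-like (2), B or plasma-like (0), lymphatic endothelial-like (3) and neutrophil-like nuclei (10), and for both differences between classes (0). In neutrophil-like nuclei the split of MGNS 1, MGNS 2 and MGHS 2 against the others gave those 10. MGHS 2 gave 42 nuclei there, and the sums per animal ran from 36878 to 616212 UMIs. Whether the 10 calls reflect a structure of the samples other than the groups or these small sums was not tested.

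For lists by camera, other splits often passed more than the real one. The real split passed 8 in all keratinocyte-like nuclei (7 of 10 splits gave as many, highest other 17), 9 in all nuclei (10 of 10, highest 15), 8 in cluster 0 (6 of 10, highest 14), 13 in basal-like (6 of 10, highest 15), 7 in spinous-like (6 of 10, highest 12), 9 in granular-like (4 of 10, highest 12) and 9 in cycling keratinocyte-like nuclei (6 of 10, highest 14). It passed 10 in T or NK-like (8 of 10, highest 15), 6 in fibroblast-like (9 of 10, highest 16), 11 in blood endothelial-like (2 of 10, highest 11), 8 in smooth muscle or pericyte-like (7 of 10, highest 12), 10 in macrophage or dendritic-like (7 of 10, highest 15), 4 in B or plasma-like (7 of 10, highest 12), 7 in lymphatic endothelial-like (6 of 10, highest 11) and 1 in neutrophil-like nuclei (10 of 10, highest 11). Splits that mix the groups passed 12 against 4 lists in B or plasma-like nuclei and 11 against 1 in neutrophil-like nuclei, so camera at its preset correlation can pass lists for groupings that mix MGNS and MGHS.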
